A study of Mus musculus with 24 samples.

How the data were processed

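Lung RNA of 24 mice was measured on Illumina bead arrays, 1 array per mouse. The mice belonged to the AIRmax and AIRmin lines, were male or female, and had received urethane or saline, which gives 8 cells of 3 mice. Groups and mouse numbers were taken from the sample titles, and no mouse number occurred more than once, so no mice were paired. Each array was taken as a separate mouse because the titles number the mice.

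The values analysed are the deposited intensities of the series' value table, on a linear scale, for 25697 probes. Per the file headers, the authors also made a table of non-normalized signals with detection p-values and a table that was quantile normalized and filtered at a detection p of 0.05. The submitters' processing notes name BeadStudio, with no version. The sorted values of the deposited table differed by at most 0.871% between arrays, with a median of about 370.5, a lowest value of 104.7 and a highest of 70078, so they were treated as already quantile normalized and not background-subtracted. How the background was handled before deposit is not given in the sources used here. The 72 columns of per-array values in the other tables (24 signal and 24 detection p columns in the non-normalized table, 24 signal columns in the filtered table) are named by slide and position, match no sample label, and were not used. Their probe identifiers and gene symbols were used. Slide was therefore not available as a batch term, and a relation between slide and group stays open.

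The plan written before the data were examined was to normalize the non-normalized signals and to filter on detection p. Because those columns could not be assigned to mice, the plan's fallback was used, the log2 of the deposited values, with no further normalization. The detection filter was replaced by a background limit from the values themselves. The mode of all log2 values was 7.40, the SD of values below the mode was 0.210, and the limit was set at the upper 0.01 quantile of that background, a log2 value of 7.89 or an intensity of about 237.7. Probes above the limit on at least 3 arrays were tested, which left 18637 probes of 13402 genes. All 11789 probes of the authors' filtered table were among them. "Above background" below refers to this limit. Where every array of a group lay at or below it, only a bound is given, as the mean of the brighter group over the limit.

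Gene names came from the non-normalized table and were updated with a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. Of the probes, 20440 carried a current symbol, 4123 an older symbol that was updated, and 1134 kept the name in the file. Each gene was represented by its probe with the highest mean log2 value, and genes whose probes passed the threshold in opposite directions are named as uncertain.

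Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model with a mean for each of the 8 cells, which share 1 estimate of the spread with 16 residual degrees of freedom. Line, urethane and sex effects average the cells with equal weight, and interactions are differences of those effects. P-values were adjusted by Benjamini-Hochberg over all tested probes, and an adjusted p under 0.05 is a call. Log2 differences are given with the standard error of the model. On simulated data with the spread of the 18637 probes, 97% of probes with a log2 change of 1 and 69% of those with 0.5 were recovered for the line difference in saline mice. For the interaction of line and treatment, 90% and 35% were recovered.

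Lists of genes (46, with at least 5 measured members) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Lists of stratified squamous epithelium, hepatocyte, epidermis and hair, and stomach gland genes were written after the data were examined. A list score is the mean, over a list's genes, of a mouse's log2 value minus the gene's median over the 24 mice. The genes named were chosen by a rule fixed beforehand. It takes the 10 largest positive and 10 largest negative log2 differences among called genes with an official symbol in each line, urethane and sex comparison, or all called genes where fewer than 20 passed. It takes 5 of each direction for interactions and up to 4 called members of each list that passed or had at least 3 called members (2 members by p where none was called). It also always takes a set of inflammation, tumour, lung and sex-linked genes. A selection of these is printed, and some genes the rule takes are not reported here.

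The alternatives were an offset of 16 before log2, no filter, a filter at 12 arrays, a fit of only the arrays compared, no sex term, a trended robust prior, array weights, each mouse left out in turn, other set tests and another choice of probe. Chosen after seeing the data were a normexp correction of the deposited values, the authors' probe list, list scores as covariates, and fits without doubted mice. The number of arrays limits the precision of every value.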

Results

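Transcript levels were measured in lung parenchyma of mice from the AIRmax and AIRmin lines, bred for a high and a low acute inflammatory reaction. The mice had received 2 intraperitoneal injections of urethane (1 mg per g of body weight), a carcinogen that induces lung tumours in mice, or saline, 48 h apart. Lungs were taken 21 days later. Each combination of line, sex and treatment held 3 mice, so each line had 12 mice and each line under each treatment had 6. Correlations between arrays over the tested probes ran from 0.934 to 0.994, and no pair of arrays was identical.

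The arrays also held transcripts of tissues other than lung. Genes of skeletal muscle and of stratified squamous epithelium were high in part of the mice, among them 5 of the 6 AIRmin saline mice, whose squamous scores were 2.76 to 3.70. Squamous scores of the 6 AIRmax saline mice did not exceed 0.831. AIRmax female urethane mouse 4 had a hepatocyte score of 4.94, against at most 0.450 in the other AIRmax urethane mice. In the library labelled female of AIRmin saline mouse 20, the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had log2 signals of 12.8, 11.4 and 9.16, where the 12 males averaged 13.1, 11.4 and 9.17. Its signal for Xist, the transcript of the inactive X chromosome, was 7.91, where the other 11 females averaged 11.1 ± 0.591 (SD). Xist was 7.74 to 8.06 in the 12 males. At these genes the library thus had the pattern of a male, and the main fit kept it under its label.

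**Figure D1:**
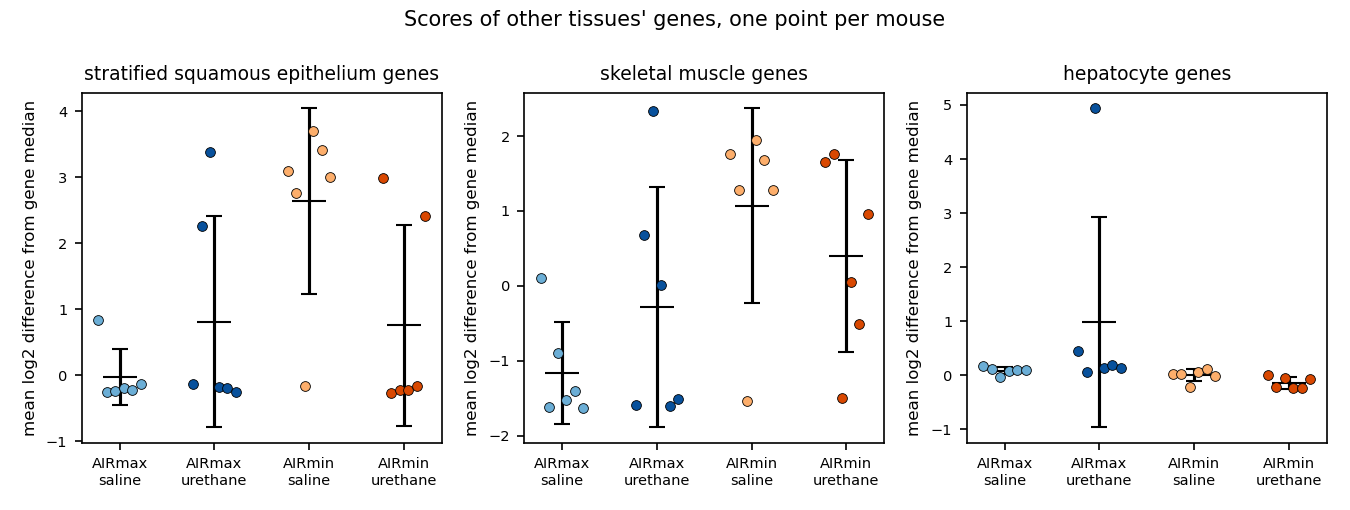
Scores of stratified squamous epithelium, skeletal muscle and hepatocyte genes, as the mean log2 difference from each gene's median over all mice, in the 4 combinations of line and treatment. Points are mice (n = 6 per group), horizontal bars are means and vertical bars are SD, and the hepatocyte score of 4.94 belongs to AIRmax female urethane mouse 4.

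The first comparison asked how the lungs of the lines differed. Over all mice, H2-Aa, the alpha chain of the class II molecule I-A, was higher in AIRmax by 5.13 ± 0.19 (log2, SE) and lay above every AIRmin mouse in 12 of 12 AIRmax mice (adjusted p = 5.25e-13). Psmb9, a subunit of the immunoproteasome, was higher by 3.54 ± 0.18, and H2-Ob, above background in 5 of 12 AIRmin mice, by 2.56 ± 0.19. Gbp2b, an interferon-inducible guanylate-binding protein, averaged 12.82 ± 0.483 (log2 signal, SD, n = 12) in AIRmax and 8.82 ± 0.574 in AIRmin. H2-Ea, the alpha chain of the class II molecule I-E, went the other way, at -5.60 ± 0.80, and was above background in 4 of 12 AIRmax and 12 of 12 AIRmin mice. Its log2 signal was 12.553 or more in these 4 AIRmax mice and 7.778 or less in the other AIRmax mice. The mean difference of H2-Ea therefore describes neither set of AIRmax mice. H2-Aa and H2-Ea had 1 tested probe each, so a sequence variant under the probe was not tested for either gene. Aldh1a7, an aldehyde dehydrogenase, was at or below background in all 12 AIRmax mice and at least 19.7-fold higher in AIRmin (adjusted p = 5.48e-14). Adh7, an alcohol dehydrogenase, was at least 11.1-fold higher in AIRmin (adjusted p = 6.1e-07). Among the other large differences, Enpp5 (3.08 ± 0.09), Abhd16a (3.08 ± 0.46), Serpina3h (3.01 ± 0.61), Cops8 (2.66 ± 0.50) and Serpina1b (2.46 ± 0.55) were higher in AIRmax. Serpina1b differed by 3.26 ± 0.78 in urethane mice, which include mouse 4 with its high hepatocyte score. How far mouse 4 carries the Serpina1b difference is not given here. Fgfr1op2 was higher by 3.48 ± 0.30 at its brightest probe and by 0.23 ± 0.06 at its other tested probe (adjusted p = 0.00904), so the size of its difference is uncertain. Sspn was lower and above background in 1 of 12 AIRmax and 12 of 12 AIRmin mice. Bhlhe40 (-2.39 ± 0.24) and Arl16 (-2.12 ± 0.12) were lower too. In all, 1206 probes were higher and 1205 lower in AIRmax. With scores of squamous, skeletal muscle and hepatocyte genes as covariates 753 probes were called, with array weights 3748, and 661 in an additive model without the 9 mice whose squamous score was above 1. The H2-Ea, Abhd16a and Cops8 calls ended with the 3 scores.

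**Figure D2:**
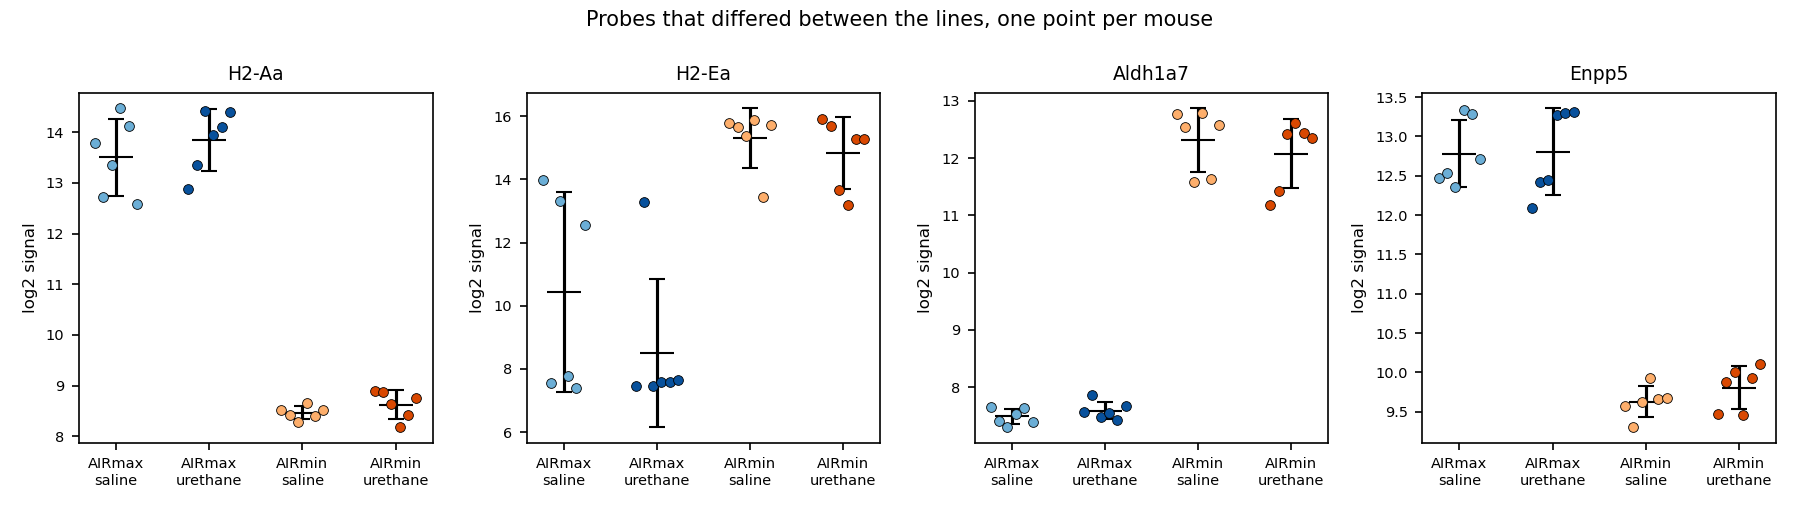
Log2 signals of H2-Aa, H2-Ea, Aldh1a7 and Enpp5 in the 4 combinations of line and treatment. Points are mice (n = 6 per group), horizontal bars are means and vertical bars are SD, and Aldh1a7 averaged 7.49 in AIRmax saline and 12.31 in AIRmin saline mice.

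Among the fixed lists, 8 of 15 measured genes of MHC class II presentation were higher in AIRmax and 1 was lower (10 were called when adjusted over the list alone, 9 higher and 1 lower; camera adjusted p = 0.000174). With an estimated correlation the adjusted p = 0.523. Of 24 cholesterol and fatty acid synthesis genes 10 were higher and none lower (12 adjusted over the list alone), among them Dhcr7 (0.67 ± 0.09) and Fads2, a fatty acid desaturase (0.38 ± 0.06). The camera adjusted p was 0.000138, and the adjusted p = 0.426 with an estimated correlation. Of 16 natural killer and cytotoxic cell markers 9 were higher (10 adjusted over the list alone), among them Tbx21, the transcription factor T-bet (0.58 ± 0.08), and the chemokine Ccl5 (1.08 ± 0.16), and the list's adjusted p = 0.426 with an estimated correlation. Of 25 neutrophil and granulocyte markers 4 were higher and 1 lower (8 and 1 adjusted over the list alone). The chemokine receptor Cxcr2 was higher by 1.97 ± 0.30 and Fpr2 was lower, at -0.65 ± 0.18, and the adjusted p = 0.523 with an estimated correlation. The neutrophil score was 1.635, 1.028, 0.837 and 0.547 in AIRmax male mice 24, 1, 21 and 2. In the other AIRmax mice it was -0.316 to 0.29, within the AIRmin range of -0.438 to 0.399. S100a8 was higher by 0.85 ± 0.27 (adjusted p = 0.0446) and Il1b by 0.98 ± 0.28 (adjusted p = 0.025), while S100a9 differed by 0.98 ± 0.35 (adjusted p = 0.0725). With the squamous score as a covariate S100a8 and Il1b were no longer called. Of 15 circadian clock genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with Nr1d2 at -0.88 ± 0.14 and Dbp at -1.90 ± 0.36. Npas2, at or below background in all 12 AIRmin mice, was at least 1.26-fold higher in AIRmax. For this list the adjusted p = 0.426 with an estimated correlation. Of 12 mast cell, basophil and eosinophil markers 5 were lower (5 adjusted over the list alone), including the mast cell proteases Tpsb2 (above background in 1 of 12 AIRmax and 9 of 12 AIRmin mice) and Cma1 (-0.38 ± 0.08), and the adjusted p = 0.523 with an estimated correlation. Catalase, Cat, was higher by 1.20 ± 0.08 and Srxn1, a sulfiredoxin, by 1.41 ± 0.17. They belong to the 45 glutathione and NRF2 response genes, of which 3 were higher and 8 lower (4 and 12 adjusted over the list alone).

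Slc11a1, a macrophage divalent metal transporter, differed by 0.30 ± 0.13 at its brightest probe (adjusted p = 0.121), while its 3 other tested probes were called higher in AIRmax by 0.62 ± 0.15, 0.50 ± 0.14 and 0.62 ± 0.14 (adjusted p = 0.00871, 0.026 and 0.00646). Cyp2e1, which oxidizes urethane, differed by 0.09 ± 0.39 (adjusted p = 0.916). Its signal was 15.9 in mouse 4 and 11.1 to 12.9 in the other 23 mice. In saline mice, which do not include mouse 4, it differed by -0.07 ± 0.56 (adjusted p = 0.97). The club cell gene Scgb1a1 and the surfactant gene Sftpc had mean log2 signals of about 16 in both lines, near the top of the range, and differed by 0.02 ± 0.03 each (adjusted p = 0.616 and 0.678). Both directions were called for 20 genes, depending on the probe, among them Casp9, Elf5 and Siglech, and the direction of these is uncertain.

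In saline mice alone, the line difference again included H2-Aa (5.04 ± 0.27), Psmb9 (3.53 ± 0.26), Enpp5 (3.15 ± 0.13) and Csrnp1 (2.61 ± 0.29), all higher in AIRmax. Aldh1a7 was at least 21.4-fold and Sspn at least 20.7-fold higher in AIRmin. The negative end also held epithelial genes of stratified squamous tissue, Krt13 (-5.92 ± 1.71), Lor (-5.91 ± 1.72) and Crct1 (-5.28 ± 1.45). Krt13 and Crct1 were above background in 1 of 6 AIRmax and 5 of 6 AIRmin saline mice each. Of the 20 measured skeletal muscle genes 14 were lower in AIRmax (17 adjusted over the list alone), among them Tnnt3 (-3.07 ± 0.72), and the adjusted p = 0.389 with an estimated correlation. These genes move with the squamous score, which was 2.76 or more in 5 of the 6 AIRmin saline mice. Krt13, Lor and Crct1 reversed with that score as a covariate, which adds no separate evidence because they belong to or follow it. In saline mice the score also nearly follows line, so the covariate can remove line differences as well. The comparison called 1244 probes, 617 higher and 627 lower in AIRmax. With the squamous score as a covariate it called 282, with array weights 3052, and without mouse 20, 10, 24 or 3 it called 689, 767, 773 or 809.

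In urethane mice, 293 probes were higher and 371 lower in AIRmax. H2-Aa (5.22 ± 0.27), Gbp2b (4.03 ± 0.32) and Abhd16a (3.97 ± 0.65) led the positive end. H2-Ea (-6.32 ± 1.14, above background in 1 of 6 AIRmax mice), Anxa4 (-2.38 ± 0.36) and Cdh16 (-2.17 ± 0.26) were among those at the negative end. Casp9 was higher at its brightest probe and lower at another and is uncertain. Of the probes called higher in saline mice and in urethane mice, which share no animals, 191 were common to both, where 9.70 would be shared by independent lists. For lower probes 167 were common, where 12.5 would be. Both comparisons use the same estimate of the spread for each probe, so their lists are not fully independent. With only the arrays of urethane mice in the fit, 341 probes were called.

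The second comparison asked what differed in the lung 21 days after urethane. Targets of the tumour suppressor p53 were higher after urethane in both lines. Gdf15, a stress-induced cytokine, rose by 2.36 ± 0.15 (log2, SE), Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 1.49 ± 0.10, Phlda3, an inhibitor of Akt, by 1.05 ± 0.07, and Ccng1, cyclin G1, by 0.89 ± 0.04. For each of these 4 genes, all 12 urethane mice lay above all 12 saline mice (adjusted p = 7.6e-09, 8.08e-09, 8.08e-09 and 3.79e-10). Of 34 measured p53 target and DNA damage genes 14 were higher and none lower (19 higher and 1 lower adjusted over the list alone). The camera adjusted p was 2.52e-27, and the adjusted p = 1.03e-05 with an estimated correlation, where no other list passed in this comparison. Sesn2, a sestrin (0.78 ± 0.09, and 0.35 ± 0.05 at its other probe), Gtse1 (0.94 ± 0.13), Plau, the urokinase plasminogen activator (0.79 ± 0.08), Mmrn2 (0.80 ± 0.09), Exoc4 (0.79 ± 0.07) and Ces2e (0.98 ± 0.13, above background in 4 of 12 saline mice) were also higher, as was Bax, a promoter of apoptosis (0.54 ± 0.06).

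**Figure D3:**
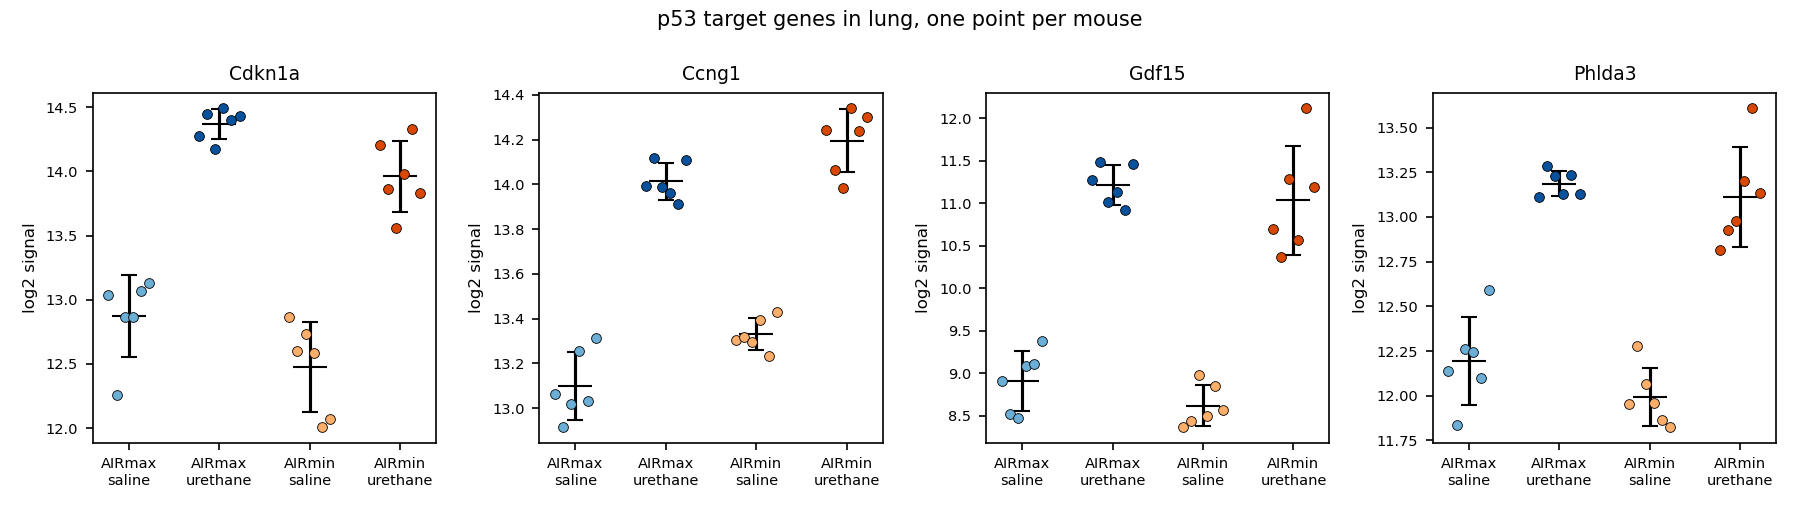
Log2 signals of Cdkn1a, Ccng1, Gdf15 and Phlda3 in the 4 combinations of line and treatment. Points are mice (n = 6 per group), horizontal bars are means and vertical bars are SD. Gdf15 averaged 8.91 in AIRmax saline and 11.21 in AIRmax urethane mice.

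Genes lower after urethane included Cxcl13, a chemokine that attracts B cells (-0.88 ± 0.20), the chemokine receptor Ccr6 (-0.57 ± 0.13, and -0.35 ± 0.10 with an adjusted p of 0.139 at another probe), the macrophage scavenger receptor Cd163 (-0.62 ± 0.12), and the growth factor binding proteins Igfbp6 (-0.69 ± 0.12) and Igfbp3 (-0.53 ± 0.10). Xpnpep2 (-0.73 ± 0.14, and -0.26 ± 0.06 with an adjusted p of 0.0573 at another probe), Dpysl5 (-0.68 ± 0.08) and Kif26b (-0.68 ± 0.08) were lower too. Of 20 smooth muscle and pericyte markers 4 were lower (7 adjusted over the list alone), among them Tpm2 (-0.50 ± 0.08) and Acta2, smooth muscle actin (-0.22 ± 0.05), and the adjusted p = 0.170 with an estimated correlation. None of 19 B cell and plasma cell markers passed over all probes and 10 were lower adjusted over the list alone. Cd79b differed by -0.48 ± 0.11 (adjusted p = 0.0514). That list passed camera at the preset correlation, and its adjusted p = 0.241 with an estimated correlation. Of 28 ciliated cell markers only Tppp3 passed, at -0.49 ± 0.07, and the adjusted p = 0.432 with an estimated correlation. Differences in S100a8 (-0.62 ± 0.27, adjusted p = 0.356) and Il1b (-0.42 ± 0.28, adjusted p = 0.571) did not pass. In all, 82 probes were higher and 51 lower. With array weights there were 499 calls, 290 higher and 209 lower. Without mouse 4 there were 200, without mouse 24, 18 or 22 there were 86, 87 or 87, and without the 9 mice with a squamous score above 1 there were 35. Calls of Cxcl13 and Ccr6 ended in that fit, without a filter on dim probes and with the squamous score as a covariate, and those of Ces2e, Mmrn2, Xpnpep2, Igfbp6 and Igfbp3 ended in that fit.

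Within AIRmax, urethane was followed by higher Gdf15 (2.30 ± 0.21), Ddit4l (1.06 ± 0.20), Slc19a2, a thiamine transporter (0.87 ± 0.12), and Ephx1, microsomal epoxide hydrolase (0.82 ± 0.09). Cdkn1a averaged 12.87 ± 0.319 (log2 signal, SD, n = 6) in AIRmax saline and 14.37 ± 0.120 in AIRmax urethane mice. Dusp26 (-0.87 ± 0.14), Tnn (-0.86 ± 0.15) and Sox17, an endothelial transcription factor (-0.54 ± 0.11, and -0.33 ± 0.09 with an adjusted p of 0.214 at another probe), were lower. Within AIRmin, Gdf15 (2.42 ± 0.21), Cdkn1a (1.49 ± 0.14), Ces2e (1.44 ± 0.19, above background in 1 of 6 saline mice) and Scn3b, a sodium channel subunit (1.29 ± 0.21, and 0.05 to 1.01 at its 3 other tested probes, which were not called), were higher, and Il12a (-0.66 ± 0.11) and Tpm2 (-0.67 ± 0.12, and -0.95 ± 1.06 and -0.31 ± 0.15 at its 2 other tested probes, which were not called) were lower. Of the 34 p53 target and DNA damage genes 11 were higher in AIRmax and 12 in AIRmin (15 and 18 adjusted over the list alone), and both lists passed with an estimated correlation (adjusted p = 6.14e-05 and 3.34e-05). AIRmax had 28 higher and 10 lower probes and AIRmin 38 higher and 10 lower. Of the higher probes 19 were common to both lines, which share no animals, where independent lists would share 0.0571. The lists are not fully independent, because both use the same estimate of the spread for each probe. Of the 10 lower probes of each line 2 were common, where independent lists would share 0.00537, and 7 of the 10 in AIRmax had the same sign in AIRmin. Over all tested probes the log2 changes of the lines had a Pearson r of -0.147 and a Spearman rho of 0.185, across probes, which are not independent replicates. With a positive rho beside it, the negative r alone does not establish opposite responses. High scores of other tissues lay in AIRmin saline mice (squamous 3.70 in mouse 19) and in AIRmax urethane mice 2 (squamous 2.256) and 4 (squamous 3.378, hepatocyte 4.94). AIRmin urethane mice 7 and 17 had high squamous scores too (2.996 and 2.419). The correlation was not computed without such mice. In AIRmax the count was 18, 19, 19, 20 or 24 without mouse 2, 21, 24, 22 or 12, 67 with array weights, and 20 with only the AIRmax arrays in the fit, which ended the calls of Slc19a2 and Sox17. In AIRmin it was 28 without mouse 20, 178 with array weights and 25 with the squamous score as a covariate, which ended the calls of Scn3b, Tpm2 and Il12a.

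Whether the lines responded differently to urethane was tested as an interaction. The difference between the Cdkn1a responses was 0.01 ± 0.19 (AIRmax minus AIRmin, adjusted p = 0.996). With limma no probe passed, and 1169 had an unadjusted p under 0.05. Differences of the size simulated at a log2 change of 0.5 were recovered for 35% of probes, so many differences of that size would not have been detected with these mice. Without mouse 17 or 10 there were 2 or 1 calls. Camera at the preset correlation called 13 of 46 lists for this interaction, while 0 passed with an estimated correlation and 0 with fry. The preset correlation thus called lists where no probe passed.

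The largest log2 differences between the sexes among called genes were at Xist and Y-linked genes. Xist was higher in mice labelled female by 2.94 ± 0.28 and Kdm6a, an X-linked histone demethylase, by 0.62 ± 0.09. Ddx3y (-2.46 ± 0.21), Eif2s3y and Kdm5d were lower, with Eif2s3y and Kdm5d above background in 1 of 12 mice labelled female and in 12 of 12 males. These values include the library of mouse 20, labelled female but with a male pattern. Its inclusion makes the differences at Xist and the Y-linked genes smaller. Pbdc1 (0.46 ± 0.06, and 0.12 ± 0.05 with an adjusted p of 0.361 at another probe) and Fam78a (0.43 ± 0.08) were higher in females, and Itgbl1 (-0.77 ± 0.11) and Gpx3, a secreted glutathione peroxidase (-0.29 ± 0.06), were lower. None of 17 platelet and megakaryocyte genes passed over all probes and 15 were lower in females adjusted over the list alone, and the adjusted p = 0.469 with an estimated correlation. In all, 7 probes were higher and 14 lower in females. Without mouse 9, 5 or 8 there were 51, 50 or 41 calls, and without mouse 15, 7, 18 or 3 there were 13, 12, 12 or 12, and with array weights 61. Calls of Fam78a and Gpx3 ended with the squamous score as a covariate. With limma no probe passed for the interaction of sex with line (856 at an unadjusted p under 0.05) or with treatment (1198). Without mouse 9 there were 5 calls for sex and line and without mouse 1, 11, 17 or 22 there was 1, and without mouse 1 or 17 there was 1 for sex and treatment. Camera at the preset correlation called 21 lists for sex and line and 12 for sex and treatment. With an estimated correlation 1 and 0 passed, and with fry 0 for each.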

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

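Tests of the squamous, skeletal muscle and hepatocyte scores within groups were chosen after the scores had been seen, while the tests of covariates, other probes, neighbouring genes and other splits of the mice were written before their results. In the 272 combinations of a list or gene with a line and treatment that were examined for a mouse far from the other 5, 23 were found, and chance alone gives about 1 in 20.

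AIRmin male saline mouse 18 stood below the other AIRmin saline mice in skeletal muscle genes (-1.53) and in stratified squamous epithelium genes (-0.158), and AIRmax male saline mouse 9 stood above the other AIRmax saline mice in the latter (0.831). Within the cells of the design, 15 of 20 skeletal muscle genes rose with the squamous score, which is consistent with tissue of the oesophagus, whose muscle is striated in mice, having been taken with the lung. AIRmin female urethane mouse 8 goes against 1 shared tissue in every mouse, with a skeletal muscle score of 1.76 and a squamous score of -0.269. Smaller departures were AIRmax mice 5 (0.017 and -0.178) and 12 (-0.9 and -0.235) and AIRmin mice 14 (0.052 and -0.226) and 15 (-0.514 and -0.161). The lowest muscle score was -1.63, in AIRmax male saline mouse 24. The source of the muscle transcripts in these mice stays open. Only 1 of 10 epidermis and hair genes rose with the score, which argues against skin, and 0 of 9 stomach gland genes did. The score differed between the lines by -1.31 (AIRmax minus AIRmin, permutation p = 0.0469, two-sided), and the lines overlapped. The permutation shuffled line over all 24 mice without regard to sex or treatment. Because the squamous list was written after the data were examined, this p is not independent support for a line difference. Overlap had been set down as evidence against a line difference, but it excludes only a difference present in every mouse. In urethane mice the score was high in AIRmax mice 2 and 4 (2.256 and 3.378) and in AIRmin mice 7 and 17 (2.996 and 2.419). It was -0.137 or less in the other urethane mice of both lines. The difference thus lay in saline mice, which argues against a line difference that holds under both treatments. Dissection and a line difference limited to saline mice cannot be told apart from this score. With the squamous score as a covariate, 0 of the 14 skeletal muscle genes called lower in AIRmax saline mice stayed called, and their median log2 difference went from -2.26 (median SE 0.576) to -0.588 (median SE 0.497).

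AIRmax female urethane mouse 4 had a hepatocyte score of 4.94, a Cyp2e1 signal of 15.9, and high scores for T cell (1.17), thymus (1.57) and complement and coagulation genes (0.782). Its skeletal muscle score of 2.33 was the highest of all 24 mice, and its squamous score of 3.38 was the highest of the AIRmax mice. Its scores for alveolar type 2 (-0.277), endothelial (-0.269) and p53 target genes (0.11) were the lowest of the AIRmax urethane mice. Of 32 measured hepatocyte genes 30 were highest in this mouse of all 24, with Ahsg at 14.9 and Apoa2 at 16.1 against at most 8.44 and 8.73 in the other 23 mice, which is consistent with liver RNA in the sample. Of the other 5 AIRmax urethane mice 2 lay above the highest AIRmax saline mouse in hepatocyte score, so a small urethane effect on these genes in AIRmax stays open. AIRmin showed no such rise, with scores of -0.245 to -0.002 in urethane mice and -0.211 to 0.113 in saline mice.

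AIRmax female saline mouse 12 had a circadian clock score of 0.393, against at most -0.58 in the other AIRmax saline mice. It also had the lowest alveolar type 2 (-0.387) and fibroblast and matrix (-0.201) scores and the lowest Cdkn1a signal (12.3) of that group. AIRmin male saline mouse 19 had the highest neutrophil score (0.399), S100a9 signal (13.9) and Il1b signal (11.2) of its group. AIRmin female saline mouse 23 was lowest in eicosanoid (-0.105) and thymus (-0.182) scores, and AIRmax male saline mouse 24 was highest in platelet genes (0.903). Kdm5c was lowest in AIRmax female urethane mouse 5 (8.66) among AIRmax urethane mice and Ddx3x in AIRmax male saline mouse 9 (10.3) among AIRmax saline mice. The 18 hypoxia response genes had a median interaction of line and sex of -0.175 (camera adjusted p = 0.000332, and adjusted p = 0.0303 with an estimated correlation), with no member called.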

How the results depend on the processing

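The normexp and quantile steps from non-normalized signals, median scaling, the authors' filtered values and slide as a block were not run, because those columns could not be assigned to mice, and the value table planned as an alternative became the main data. Covariates, fits without doubted mice, normexp on deposited values and the authors' probe list were chosen after seeing the data. No paired analysis was possible because no mouse number is shared between groups. With an offset, no filter, the stricter filter and normexp on the deposited values, every count of calls stayed within 1.5 times its value. So did the counts run with no sex term (the line and urethane comparisons and their interaction) and with a trended prior (all counts except that of lists).

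With array weights the calls were 3748 for the line difference in all mice, 3052 in saline mice, 499 for urethane in both lines, 67 in AIRmax, 178 in AIRmin, 61 for sex and 1 for the interaction of line and sex. With only the arrays compared they were 341 for the line difference in urethane mice and 20 for urethane in AIRmax, with fewer arrays to estimate the spread. With the authors' probe list, 810 were called for the line in saline mice, and 77 of 136 called named genes were tested and kept. With the squamous score as a covariate, calls were 282 for the line in saline mice (245 of them shared with the main analysis in the same direction), 25 for urethane in AIRmin and 13 for sex. With 3 scores they were 753 for the line in all mice, 225 in saline mice, 414 in urethane mice and 30 for urethane in AIRmin. Without the 9 mice with a squamous score above 1 (10 AIRmax and 5 AIRmin mice left) they were 661 for the line, 35 for urethane and 8 for sex, with fewer mice. For the array weights the cause was not tested. Over all comparisons 162 lists were called, against 4 with an estimated correlation and 42 with fry for 1 direction.

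Direction reversed with the squamous score as a covariate for Krt13 (0.58), Lor (0.57) and Crct1 (0.28) in saline mice. With 3 scores it reversed for Krt13 (0.89), Lor (0.91), Crct1 (0.65), Myh8 (0.63) and Lce3b (0.020) in saline mice and for Myh8 (0.59), Tnnc2 (0.51) and Mylpf (0.31) in all mice. These genes belong to or follow the scores that were removed. Krtdap in all mice reversed without the mice with a high squamous score (0.024), and Casp9 in urethane mice reversed at the probe with the largest t (-0.58).

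With each mouse left out, calls ranged from 1934 to 2921 for the line in all mice, 689 to 1511 in saline mice and 451 to 716 in urethane mice. They ranged from 86 to 200 for urethane in both lines, 18 to 45 in AIRmax and 28 to 62 in AIRmin, and from 12 to 51 for sex. The interactions ranged from 0 to 2 (line and treatment), 0 to 5 (line and sex) and 0 to 1 (sex and treatment). List calls ranged from 153 to 179 and named genes from 111 to 130. Mice that moved a count by over 1.5 times were 20 (689), 10 (767), 24 (773) and 3 (809) for the line in saline mice, and 4 (200), 24 (86), 18 (87) and 22 (87) for urethane in both lines. For urethane in AIRmax they were 2 (18), 21 (19), 24 (19), 22 (20) and 12 (24), and for urethane in AIRmin 20 (28). For sex they were 9 (51), 5 (50), 8 (41), 15 (13), 7 (12), 18 (12) and 3 (12). For the interactions of line and sex they were 9 (5), 1, 11, 17 and 22 (1 each), of line and treatment 17 (2) and 10 (1), and of sex and treatment 1 and 17 (1 each). Without mice 4 and 20 together every count stayed within 1.5 times. The cause of each was not tested. Signals near background and near the top of the range limit what can be measured for dim and for very abundant transcripts.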

Other observations

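The tests of other probes, neighbouring genes and other splits were written before their results were seen.

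Genes called between the lines often lay beside each other. Of 1736 called genes with a known place among 12733, 530 had a called neighbour, where 10000 shuffles of the calls gave a median of 440 and at most 525 (permutation p = 1e-04, the smallest these shuffles can give). For the 100 genes called after urethane the count was 0, and the shuffles had a median of 2 and ran from 0 to 10. With so few calls this count cannot show or exclude clustering, so it is no contrast to the line result. The excess for the line calls is what inherited chromosome blocks that differ between the lines could give, although clusters of genes regulated together would give the same count. For 794 called genes with another tested probe, that probe had the same direction in 81.2% (exact 95% interval 78.3 to 83.9%), which argues against sequence variants under single probes as the whole cause. It passed the threshold in the same direction in 26.2% and in the opposite direction for 16 genes, so variants may still account for part of the differences.

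In 100 splits of the mice within sex and treatment, or within line and sex or line and treatment for the other effects, the real one included, the line difference called 2411 probes in all mice, 1244 in saline mice and 664 in urethane mice. The highest other splits gave 276, 262 and 82, so 1 of 100 splits reached each real count. Chance is therefore unlikely, within the limit of 100 splits. The splits cannot separate line from anything that follows it, such as tissue carried along or slide. For urethane, 133 calls in both lines (highest other 3) and 48 in AIRmin (highest other 16) were each reached by 1 of 100 splits. Chance is unlikely here too, with the same limit for anything that follows treatment. The 38 calls in AIRmax were reached by 3 of 100 splits, the real one included, and the highest other split gave 84. Few splits reached the real count, but the others among these 3 grouped the mice otherwise than treatment did. How closely they followed treatment was not recorded. At least 1 of them called more probes than the real split, and the cause was not tested. The 21 calls for sex were reached by 1 of 100 splits (highest other 9). For the interactions of line and treatment, line and sex, and sex and treatment, the real count was 0, which all 100 splits reach by construction, so these splits say nothing about chance. Their highest other counts were 2, 11 and 56.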
